A study of Mus musculus with 8 samples.

How the data were processed

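RNA was measured by sequencing in 8 libraries of mouse CD4+ T cells. Per the labels, 4 came from the colon of recipients without T cells, 6 weeks after transfer of naive cells from control (floxed Rora) or knockout (Cd4-driven Cre, floxed Rora) mice. The other 4 were Th17 cells cultured for 4 days in 1 of 2 cytokine mixes, with 1 control and 1 knockout library per mix. All cells were treated with PMA and ionomycin for 2 hours. Per the submitters' processing notes, reads were handled with Trim Galore, Bowtie2, featureCounts, edgeR and DESeq2 on build mm10, with no roles or versions stated. The deposited values were raw read counts per gene, with no normalization, per the file headers, and whole numbers were found in each file. Strand setting and read type were not given in the sources used here.

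The colitis files held 54446 entries with Ensembl identifiers, of which 54409 occur in GENCODE release M21, and the files of cultured cells held 55341 entries with gene symbols, of which 55315 occur in that release. The annotation thus differed between the kinds of file, and they were joined by symbol for 54289 genes. In each colitis file 27 and in each culture file 26 symbols had been turned into dates. They held at most 0.269% of a library's counts and were neither named nor joined. Library totals are given with the results. Ribosomal protein genes took 3.11% to 5.95% of counts and no gene more than 1.35%. Replicate libraries were checked to be distinct, since differences within a colitis group exceeded counting error (chi-square per gene of 7.57 for control and 5.51 for knockout). Whether they are separate mice was not given in the sources used here. The p-values measure only the spread between these libraries, which may be technical. Poisson intervals of 95% cover counting error only.

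Analyses were run in R 4.3.3. Genes were tested with edgeR 4.0.16 by quasi-likelihood F-tests after filterByExpr and TMM scaling, with Benjamini-Hochberg adjustment and a threshold of 0.05. Colitis was fitted alone (2 against 2, 2 residual degrees of freedom). The cultured cells were fitted with terms for cytokine mix and genotype, which leaves 1 residual degree of freedom and takes the mixes as repeats of the genotype difference. The genotype effect in colitis minus that in culture was tested in a fit of all 8 libraries with 3 residual degrees of freedom. Within a mix, 1 library was set against 1 with no p-value. Log2 ratios used a prior count of 2, were counted at 2-fold or more where either library reached 5 CPM, and list medians were placed among 10000 random lists matched on expression. Correlations across genes are descriptions, and overlaps of calls were tested with Fisher's exact test. CPM values are TMM-scaled.

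The comparisons, the lists, the 14 fixed genes, the rule for naming others and all alternatives except library totals for single genes were chosen before the data were examined. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes when at least 5 members were tested, with Benjamini-Hochberg adjustment over the lists. The 43 lists were Th17 core, pathogenic Th17, non-pathogenic Th17, Th1, Th2, Treg, follicular helper, mTORC1 complex and positive regulators, mTORC1 negative regulators, mTORC1-responsive, glycolysis, sterol biosynthesis, fatty acid synthesis, fatty acid oxidation, ATF4 with serine and one-carbon metabolism, nuclear genes of the respiratory chain and ATP synthase, mitochondrially encoded, cytosolic ribosomal proteins, ribosome biogenesis and MYC, proliferation, immediate-early, gut homing, naive and memory, co-inhibitory receptors, cytotoxic and chemokine, ROR and clock, interferon response, TGF-β response, NF-κB, hypoxia and heat shock genes, and markers of epithelium, B and plasma cells, macrophages, neutrophils, dendritic cells, NK and innate lymphoid cells, CD8 cells, conventional T cells, fibroblasts, endothelium, erythroid cells and mast cells. They were written from general knowledge and share members.

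Named genes were Rora, 14 fixed genes of the study question, and up to 4 members per list with the smallest p-values. In each tested comparison the 8 largest changes per direction were added, among genes past the threshold with 5 CPM or more in every library of the higher group and no overlap between groups. In culture, where fewer passed, this was filled by smallest unadjusted p. Genes without an established symbol were not named under that rule, and 1 of the fixed genes is not reported here. Where the lower group had no count, a fold is given as at least the ratio to a floor of 3 counts per library.

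The methods were tested on simulated data with 200 changed genes, all picked among genes with many counts, and 5 lists of 30 genes changed 1.3-fold. In culture a simulated change had the same size in both pairs. Recovery was thus not measured for genes with few counts or for changes in 1 mix alone. The real fits called 4 genes for genotype in culture, 5173 in colitis and 9765 for the cytokine mix. Neither recovery nor scaling was thus tested at such numbers of changed genes. In edgeR 78% of 1.5-fold and 96% of 2-fold changes were recovered in the colitis design, with 8.18% of calls false. In culture these were 85%, 98% and 9.47% for genotype and 87%, 97% and 3.46% for the cytokine mix, and in the joint fit 42%, 81% and 10.0%. Of 5 changed lists among 20, camera recovered 5 with the preset correlation in each design, and 5 in colitis, 0 for either term in culture and 4 in the joint fit with an estimated one. Simulated genes varied independently, so the preset correlation was not tested on lists whose genes vary together. Alternatives were RLE scaling, no filter on low counts, the Wald test of DESeq2 1.42.0, the replicate number as a block, leaving out each colitis library, an estimated correlation, fry in place of camera, and a prior count of 0.5 or a floor of 1 CPM for single pairs. Library totals without a scaling factor were set in advance for list medians and added for single genes after seeing the data.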

Results

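RNA sequencing read counts per gene were obtained from 8 mouse CD4+ T cell libraries. RORα, encoded by Rora, is a nuclear receptor expressed in T helper 17 (Th17) cells. The series asked, by its title, about RORα and the activity of mTORC1, a kinase complex that promotes protein synthesis and glycolysis, during colitis driven by T cells. Knockout cells came from mice with floxed Rora alleles and a Cre recombinase driven by Cd4, and control cells from mice with the floxed alleles alone. In the colitis model, naive CD4+ T cells of either genotype were given to mice that lack their own T cells. CD4+ T cells were taken from the colon 6 weeks later, giving 2 control and 2 knockout libraries. For Th17 cells made in culture, naive CD4+ T cells were stimulated through CD3 and CD28 for 4 days with TGF-β and IL-6, or with IL-6, IL-1β and IL-23. Each combination of genotype and cytokine mix had 1 library and therefore no replicate. PMA and ionomycin, which activate T cells, were applied to all cells for 2 hours before RNA was extracted. The colitis libraries held 13176752 and 14967756 counts in control and 13778437 and 14440260 in knockout. The cultured libraries held 15796824 (control) and 15922696 (knockout) counts with TGF-β and IL-6, and 15252700 and 15336768 with IL-6, IL-1β and IL-23.

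Rora, the deleted gene, was lower in each knockout library than in its controls. The gene (ENSMUSG00000032238) lies on the plus strand of chromosome 9, 68653786 to 69388246 in mm10. In colitis it measured 252 and 291 CPM (counts scaled by TMM-adjusted library size) in the control libraries and 134 and 149 CPM in the knockout libraries, from 3104, 4067, 1958 and 2305 counts. The knockout mean was 52.0% of the control mean. With TGF-β and IL-6 the counts were 7881 in control (95% Poisson interval 7708 to 8057) and 3020 in knockout (2913 to 3130), which left 37.96% after scaling. With IL-6, IL-1β and IL-23 they were 2307 (2214 to 2403) and 906 (848 to 967), which left 38.8%. These intervals cover counting error only. The log2 fold change was -0.94 ± 0.09 (SE) in colitis and -1.38 ± 0.07 across both cultures, with adjusted p of 2.4e-05 and 4.0e-04 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Which part of Rora is floxed was not given in the sources used here, and reads outside that part can remain after deletion.

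Libraries of knockout CD4+ T cells from the inflamed colon had less RNA for the Th17 cytokine genes Il17a and Il17f and more for the type 2 cytokine genes Il4, Il5 and Il13. Il17a, which encodes interleukin 17A, fell from 2114 ± 160 to 588 ± 32.0 CPM (SD, n = 2 per group), and Il17f fell from 540 ± 23.9 to 137 ± 7.12 CPM. Il4 rose from 34.0 ± 4.61 to 429 ± 53.7 CPM, Il5 from 28.5 ± 1.06 to 215 ± 17.7 CPM, and Il13 from 796 ± 60.6 to 3231 ± 64.1 CPM. Il3, a growth factor for myeloid cells, rose from 5.68 ± 0.249 to 221 ± 12.3 CPM.

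Of 13101 genes tested in colitis, 5173 passed an adjusted p of 0.05 (edgeR quasi-likelihood, Benjamini-Hochberg), of which 2566 were higher and 2607 lower in the knockout. A change of at least 2-fold was found for 1074 of these, 859 higher and 215 lower. Markers of epithelium (list median 3.21), fibroblasts (1.88) and B and plasma cells (1.76) rose in the same libraries. Rises of single genes and of lists were thus not separated from a larger share of RNA from other cells. An unadjusted p under 0.05 was reached by 6304 genes, where chance would give 655. TMM scaling set the log2 fold changes -0.19 from those with library totals alone, a setting chosen for single genes after seeing the data. With library totals at least 32 of 39 list medians moved by more than the spread between replicates, and 12 changed sign, 2 of them for called lists (mTORC1-responsive, ROR and clock). With this scaling 5548 genes passed, 4291 higher and 1257 lower, so that 77.3% of calls were higher in place of 49.6%. DESeq2's Wald test called 3448. The variation between libraries of a group was 7.48% (biological coefficient of variation).

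Among the fixed genes of the study question, the Th17 receptor gene Ccr6 fell with a log2 fold change of -1.88 ± 0.15 (SE), beside Il17f at -1.98 ± 0.08 and Il17a at -1.84 ± 0.09. Il10, an anti-inflammatory cytokine gene, fell by 0.99 on the log2 scale, Il22 by 0.81, and Tnf by 0.48. The largest adjusted p of these 6 genes was 5.5e-04 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Ifng (-0.40, adjusted p = 0.0022, from 1382 to 1051 CPM) and Tbx21 (-0.34, adjusted p = 0.0051), both Th1 genes, were lower in edgeR's quasi-likelihood test and did not pass with library totals (0.058 and 0.15). Il23r, the interleukin 23 receptor gene, changed by -0.61 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.015). It no longer passed without control replicate 1 (0.077), without knockout replicate 2 (0.070), with library totals (0.071) or in DESeq2 (0.13). Csf2 changed by -0.23 with an edgeR adjusted p of 0.046, and was past the threshold neither without control replicate 1 (0.32), knockout replicate 1 (0.12) or knockout replicate 2 (0.053), nor with library totals (0.76). Il2 rose by 0.59 ± 0.11. Mtor (-0.21 ± 0.10, adjusted p = 0.13) and Foxp3 (0.09 ± 0.08, adjusted p = 0.41) did not pass in edgeR's quasi-likelihood test, although Foxp3 did with library totals (0.28, adjusted p = 0.014).

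The largest increases by the fixed rule included Il3 (5.28 ± 0.11, SE), Ighg1 (4.75 ± 0.14), an immunoglobulin constant gene, Cldn4 (4.56 ± 0.36), a tight junction gene, Car8 (4.24 ± 0.28), Adamdec1 (4.14 ± 0.30) and Krt8 (4.10 ± 0.25), a keratin of simple epithelia. Reg3b, an antimicrobial lectin gene of gut epithelium, had 3 counts in control and 212 in knockout, a ratio of 61.7 with a 95% counting interval of 20.8 to 301. Gnai1 had 6 and 181 counts, a ratio of 26.3 (11.9 to 72.7). The largest decreases were in Cd8a (-3.19 ± 0.18), Ablim3 (-2.89 ± 0.15), Krt83 (-2.78 ± 0.21), Prss12 (-2.75 ± 0.22), Tff1 (-2.16 ± 0.26), Foxs1 (-2.10 ± 0.24), Tnfrsf25 (-2.01 ± 0.09), a death receptor of the TNF family, and Il17f. Cd8a fell from 18.8 to 2.06 CPM, while Cd8b1, for the other CD8 chain, had 1.77 and 1.38 CPM and did not pass. Il17a (20730905 to 20734496) and Il17f (20777146 to 20790617) lie near each other on chromosome 1 in mm10. Il5 (53720794 to 53725106), Il13 (53631324 to 53634702), Il4 (53602982 to 53618669) and Il3 (54265303 to 54267277) lie on chromosome 11.

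**Figure D1:**
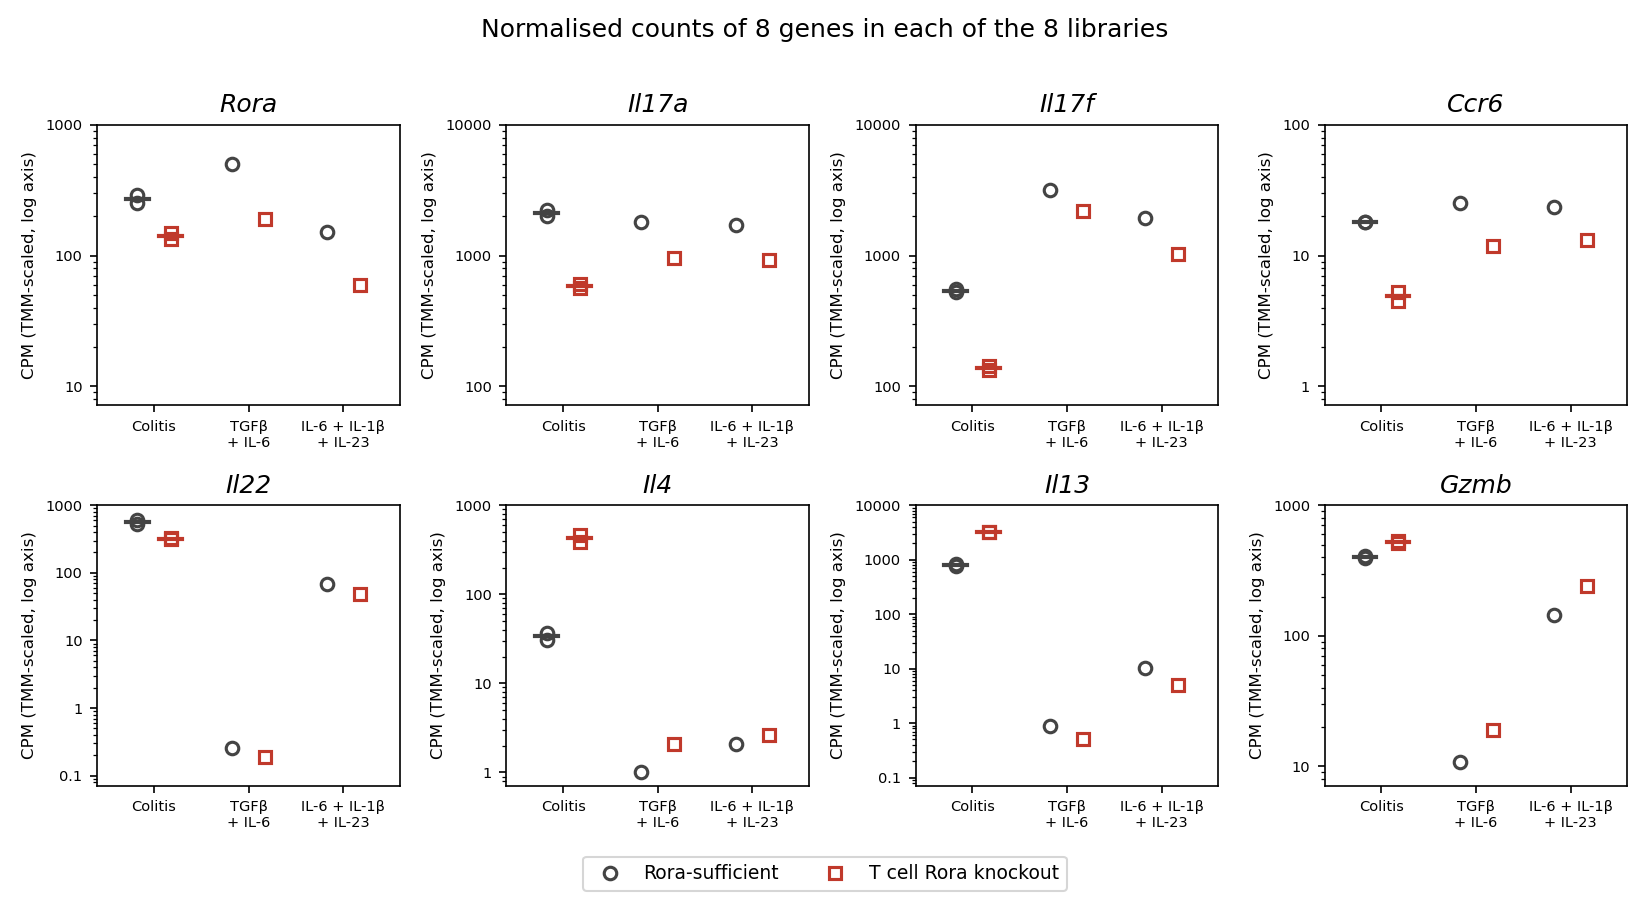
CPM (TMM-scaled, log axis) of 8 genes in each of the 8 libraries, with circles for control, squares for knockout and a bar at the mean of the 2 colitis libraries of a group. Rora, Il17a and Ccr6 sit lower in knockout in all 3 settings, while Il4 rises from 34.0 to 429 CPM in colitis and stays between 1.01 and 2.61 CPM in culture.

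Of 43 fixed gene lists, 39 had enough tested members in colitis. There, camera with a preset correlation between genes called 17 lists, 8 higher and 9 lower in the knockout. None passed with an estimated correlation (lowest adjusted p = 0.22 with an estimated correlation), while fry, which tests a list by itself and not against other genes, called 21. Of the 20 Th17 core genes, 13 fell, 2 rose and 5 did not pass (14 fell and 2 rose adjusted over the list alone). Examples beside Il17a and Il17f were Tmem176a (-1.26 ± 0.08, SE) and the transcription factor gene Batf (-1.16 ± 0.08). The list median was -0.60 (camera adjusted p = 2.0e-13; adjusted p = 0.22 with an estimated correlation). Of 11 tested Th2 genes, 8 rose, 1 fell and 2 did not pass, with the same counts adjusted over the list alone. Il4 (3.66 ± 0.12), Il5 (2.91 ± 0.10), Il13 (2.02 ± 0.08) and Gata3 (0.98 ± 0.08), the Th2 master regulator gene, led the list, and Il10 was the member that fell. The Th2 median was 0.93 (camera adjusted p = 2.3e-18; adjusted p = 0.22 with an estimated correlation).

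Of the 79 genes for cytosolic ribosomal proteins, 69 fell, none rose and 10 did not pass (72 fell adjusted over the list alone). Their median was -0.68 with quartiles of -0.83 and -0.54, and -0.49 with library totals (camera adjusted p = 6.8e-33; adjusted p = 0.39 with an estimated correlation). Rps14 (-1.20 ± 0.10, SE), Rplp0 (-1.02 ± 0.09), Rps19 (-0.98 ± 0.08) and Rpl32 (-0.91 ± 0.08) were the clearest. These genes have many pseudogene copies that can share reads, so single values are uncertain. They took 5.95% and 5.26% of all counts in the control libraries and 3.84% and 3.72% in the knockout libraries. Of 75 nuclear genes for subunits of the respiratory chain and ATP synthase, 53 fell, 1 rose and 21 did not pass (55 fell and 1 rose adjusted over the list alone), among them Cox4i1 (-0.90 ± 0.08) and Atp5h (-0.75 ± 0.08). The median was -0.43, and -0.24 with library totals (camera adjusted p = 2.9e-12; adjusted p = 0.39 with an estimated correlation). The mitochondrially encoded list was not called (1 rose, 2 fell and 7 did not pass, median 0.22, camera adjusted p = 0.85 with an estimated correlation and 0.76 with the preset one).

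Glycolysis genes fell in 13 of 26 cases, with 1 riser and 12 that did not pass, the same counts as adjusted over the list alone. Hk2, a hexokinase gene, fell from 224 to 105 CPM, and Eno1 (-0.77), Pfkl (-0.74) and the lactate dehydrogenase gene Ldha (-0.69) fell on the log2 scale. The median was -0.41, and -0.21 with library totals (camera adjusted p = 1.0e-04; adjusted p = 0.39 with an estimated correlation). Among 25 genes of the ATF4 response and of serine and one-carbon metabolism, 17 fell, 2 rose and 6 did not pass (19 fell and 3 rose adjusted over the list alone). Asns (-0.93 ± 0.08, SE), for asparagine synthetase, Atf5 (-0.86 ± 0.10) and the amino acid transporter gene Slc7a5 (-0.61 ± 0.08) were examples, and the median was -0.34, and -0.14 with library totals (camera adjusted p = 1.8e-04; adjusted p = 0.41 with an estimated correlation). Conventional T cell markers also fell in the same libraries (median -0.32, quartiles -0.43 and -0.22). The falls of the respiratory chain, glycolysis, ATF4, mTORC1-responsive, NF-κB, and ROR and clock lists were thus not separated from a lower share of T cell RNA. The Th17 core median of -0.60 lay below these quartiles, so a lower share of T cell RNA may account for part of that fall.

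Of 91 genes that respond to mTORC1, 34 fell, 17 rose and 40 did not pass (37 fell and 21 rose adjusted over the list alone). Asns, Hk2, Ldha and Sqstm1 (-0.66 ± 0.08, SE) had the smallest p-values. The median was -0.11, turned to 0.08 with library totals, and the camera adjusted p was 0.021 (adjusted p = 0.39 with an estimated correlation). Without knockout replicate 1 the list was no longer called (camera adjusted p = 0.059). The 27 genes for mTORC1 itself and its positive regulators were not called, since 8 fell, 4 rose and 15 did not pass, with the same counts adjusted over the list alone, and the median was -0.07 with TMM and 0.12 with library totals (camera adjusted p = 0.24). Slc7a5, Akt2 (-0.62 ± 0.08) and Lamtor1 (-0.59 ± 0.08) were among those that fell. Of 25 negative regulators, 7 fell, 3 rose and 15 did not pass, with Ddit4 at -0.87 ± 0.10 and Sesn1 at 1.08 ± 0.14 (median -0.15, 0.04 with library totals, camera adjusted p = 0.30).

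ROR and clock genes included 6 that fell, 2 that rose and 9 that did not pass, the same adjusted over the list alone. Arntl (-1.34 ± 0.09, SE), which encodes the clock activator BMAL1 and is a known ROR target, Hlf (-1.34 ± 0.11), Cry1 (-1.12 ± 0.09) and Nfil3 (-0.87 ± 0.08) led them. The median was -0.09 and turned to 0.11 with library totals (camera adjusted p = 0.0018; adjusted p = 0.39 with an estimated correlation). In the interferon response list 15 rose, 4 fell and 14 did not pass (17 rose and 4 fell adjusted over the list alone). It included the guanylate-binding protein genes Gbp7 (1.26 ± 0.11), Gbp3 (1.20 ± 0.08) and Gbp4 (1.16 ± 0.09), and the median was 0.28, and 0.48 with library totals (camera adjusted p = 8.7e-04; adjusted p = 0.44 with an estimated correlation). Macrophage (median 0.61) and dendritic cell markers (median 0.60) rose in the same libraries. The rises of the interferon list (median 0.27 in culture) and of the co-inhibitory list below were thus not separated from RNA of other cells. NF-κB pathway genes fell in 10 cases, rose in 2 and did not pass in 8, the same adjusted over the list alone, with Bcl3 at -1.21 ± 0.10. Their median was -0.20, and -0.01 with library totals (camera adjusted p = 0.021; adjusted p = 0.39 with an estimated correlation), and the call ended without knockout replicate 2 (camera adjusted p = 0.051). Co-inhibitory receptor genes rose in 7 cases, fell in 1 and did not pass in 6 (7 rose and 2 fell adjusted over the list alone), with Btla (0.93 ± 0.09) and Havcr2 (0.86 ± 0.09), which encodes TIM-3, as examples. The median was 0.19, and 0.39 with library totals (camera adjusted p = 0.026; adjusted p = 0.39 with an estimated correlation), and this call ended without knockout replicate 1 (camera adjusted p = 0.059) or knockout replicate 2 (camera adjusted p = 0.064).

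Lists of markers of other cell types were also tested in colitis, and 5 of them were called higher in the knockout. Of 11 tested epithelial markers, 10 rose and 1 did not pass, with Krt19 at 3.67 ± 0.30 (SE) and Krt8 going from 0.652 to 11.2 CPM. The list median was 3.21 (camera adjusted p = 7.8e-14; adjusted p = 0.22 with an estimated correlation), and in Pigr the ratio of 136 to 4 counts was 29.7 (11.3 to 110). Of 9 B cell and plasma cell markers, 7 rose and 2 did not pass (9 rose adjusted over the list alone). Jchain rose by 2.53 ± 0.10, Igkc by 1.73 ± 0.09, and the IgA constant gene Igha from 383 ± 4.30 to 1462 ± 64.6 CPM (SD, n = 2). Their median was 1.76 (camera adjusted p = 1.6e-15; adjusted p = 0.22 with an estimated correlation). Fibroblast markers rose in 10 of 12 cases, with Col3a1 at 2.64 ± 0.23 and Dcn at 2.38 ± 0.17, and only Thy1, which T cells also express, fell (median 1.88, camera adjusted p = 3.6e-07; adjusted p = 0.39 with an estimated correlation). Dendritic cell markers, which included the MHC class II gene H2-Aa (1.09 ± 0.09), rose in 5 cases, fell in 2 and did not pass in 1 (median 0.60, camera adjusted p = 0.0025; adjusted p = 0.39 with an estimated correlation). That call ended with no filter on low counts (camera adjusted p = 0.056). Macrophage markers rose in 7 of 14 cases with C1qb at 1.47 ± 0.19 (median 0.61, camera adjusted p = 0.046; adjusted p = 0.44 with an estimated correlation). That call ended without control replicate 2 (camera adjusted p = 0.10) or knockout replicate 1 (camera adjusted p = 0.055). The counts for epithelial, fibroblast, dendritic and macrophage markers were the same adjusted over the list alone.

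Conventional T cell markers fell in 12 of 16 cases, rose in 1 and did not pass in 3 (14 fell and 1 rose adjusted over the list alone). Cd3d (-0.62 ± 0.10, SE) and Thy1 (-0.57 ± 0.08) fell most clearly, and Cd4 had 1013 CPM in control and 884 CPM in knockout. The median was -0.32, and -0.13 with library totals (camera adjusted p = 8.7e-04; adjusted p = 0.39 with an estimated correlation). Endothelial markers rose in 4 of 6 cases (median 1.45, camera adjusted p = 0.095), and NK and innate lymphoid markers rose in 3, fell in 2 and did not pass in 4, neither list being called (median 0.46, camera adjusted p = 0.11). Lists with fewer than 5 tested genes had no test. Of these, neutrophil markers had 1 riser, Cxcl2, among 3, CD8 markers 1 that fell among 2, mast cell markers 2 that rose and 1 that fell among 3, and erythroid markers no tested gene.

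The other T helper and metabolic lists were not called in colitis. Pathogenic Th17 genes went both ways, with 5 that rose, led by Il3, 9 that fell, such as Cxcl3 (-1.67 ± 0.08, SE) and Ccl4 (-1.13 ± 0.08), and 5 that did not pass (camera adjusted p = 0.56). Non-pathogenic Th17 genes rose in 5 and fell in 2 of 8 cases (camera adjusted p = 0.21). Th1 genes rose in 4 and fell in 7 of 16 cases, with Cxcr3 at -0.90 ± 0.08 (camera adjusted p = 0.30). Treg genes rose in 4 and fell in 6 of 17 cases, with Nrp1 at 2.19 ± 0.17 and Ikzf2 at 1.15 ± 0.10 (camera adjusted p = 0.82). Follicular helper genes rose in 4 and fell in 3 of 10 cases (camera adjusted p = 0.61). Gut homing genes rose in 9 and fell in 7 of 20 cases, with Gpr15, a receptor that directs T cells to the large intestine, at 2.50 ± 0.13 (camera adjusted p = 0.80). Cytotoxic and chemokine genes rose in 7 and fell in 7 of 18 cases, with Gzma at 1.99 ± 0.09 (camera adjusted p = 0.76).

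Camera called none of the remaining colitis lists either. Heat shock genes rose in 6 and fell in 3 of 14 cases (camera adjusted p = 0.097), and TGF-β response genes rose in 5 and fell in 5 of 19, with Ltbp4 at 2.33 ± 0.16 (SE; camera adjusted p = 0.29). Fatty acid oxidation genes fell in 5 of 18 cases (none adjusted over the list alone; camera adjusted p = 0.35), fatty acid synthesis genes rose in 2 and fell in 3 of 14 (0.86), and sterol genes rose in 6 and fell in 4 of 24 (0.92). Ribosome biogenesis genes rose in 11 and fell in 8 of 34 cases, with Myc at -0.70 ± 0.08 (camera adjusted p = 0.98), and proliferation genes rose in 6 and fell in 10 of 40, with Mki67 at 0.73 ± 0.10 and Mcm5 at -0.64 ± 0.08 (camera adjusted p = 0.62). Immediate-early genes rose in 9 and fell in 11 of 33 cases (camera adjusted p = 0.76), naive and memory genes rose in 4 and fell in 2 of 17 (0.76), and hypoxia genes rose in 6 and fell in 4 of 16, with Vegfa at 1.28 ± 0.20 (camera adjusted p = 0.80). Adjusted over the list alone, pathogenic Th17 genes had 6 that rose, Th1 genes 5, cytotoxic genes 8 and heat shock genes 7, and follicular helper genes had 4 that fell. Apart from the fatty acid oxidation genes above, the other counts of the tested lists not called were the same. Neutrophil markers, a list without a test, had 2 that rose.

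**Figure D2:**
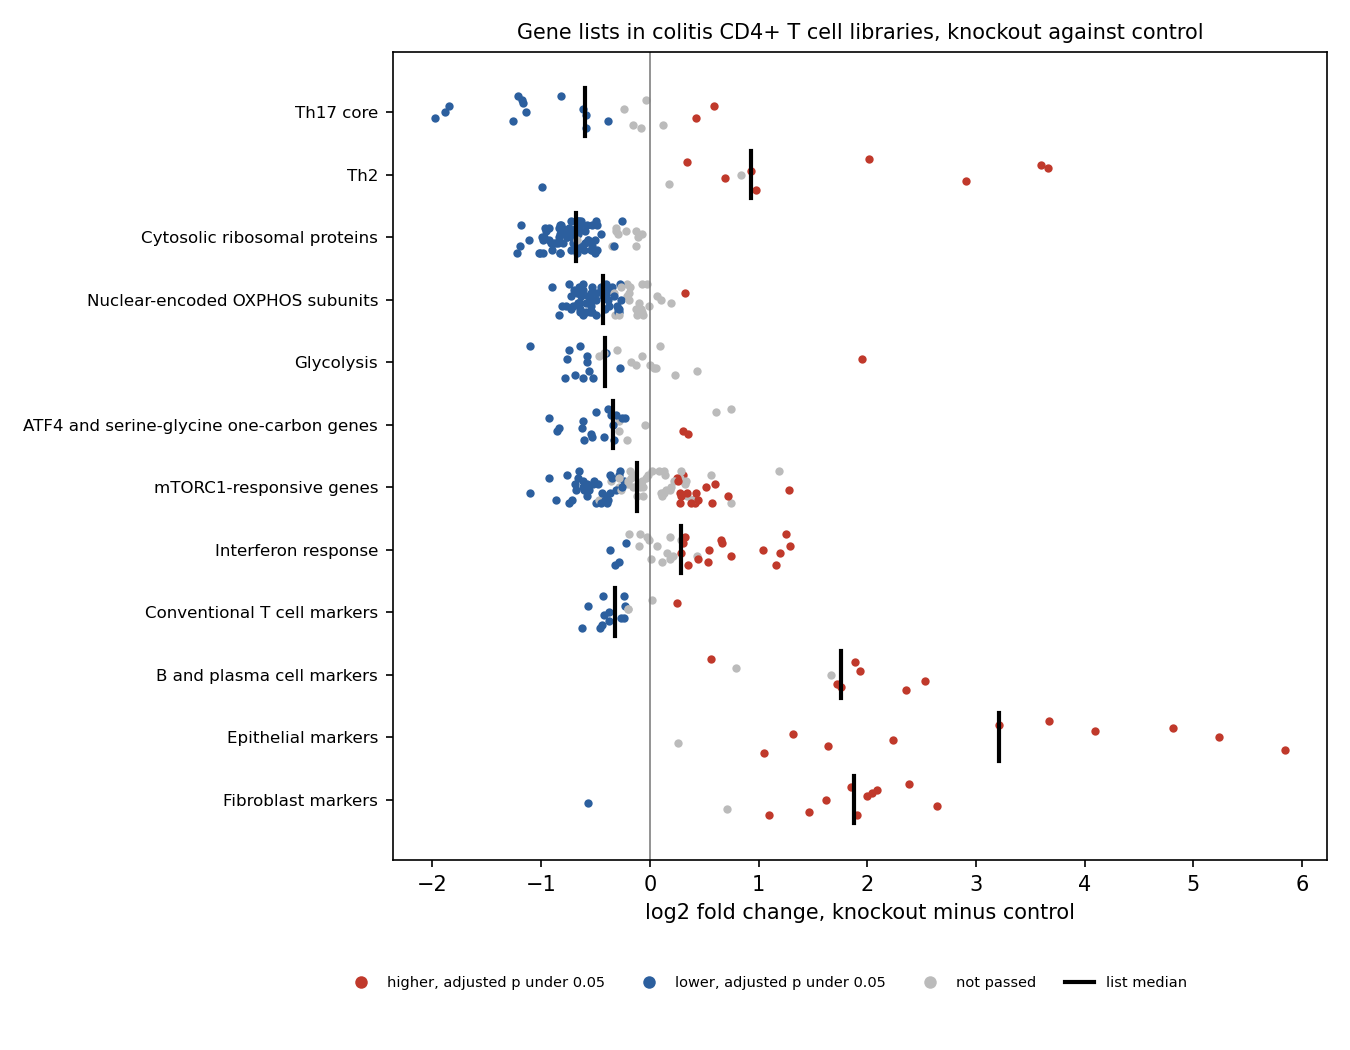
Log2 fold change (knockout minus control) of each tested gene in 12 of the fixed lists in colitis CD4+ T cells; colour marks an edgeR adjusted p under 0.05 and bars mark list medians. The ribosomal protein median lies at -0.68 and the Th2 median at 0.93, and the mTORC1-responsive median of -0.11 turned to 0.08 with library totals.

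In Th17 cells made in culture, few single genes differed between the genotypes across both cytokine mixes. Il17a fell from 1808 to 960 CPM with TGF-β and IL-6 and from 1704 to 922 CPM with IL-6, IL-1β and IL-23. Gzmb, which encodes the cytotoxic protease granzyme B, rose from 10.8 to 19.0 CPM and from 143 to 240 CPM. Of 13983 genes tested in a model with cytokine mix and genotype, 4 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test. They were Rora, Il17a (-0.90 ± 0.07, SE, adjusted p = 0.0048), Gzmb (0.77 ± 0.08, adjusted p = 0.033) and Gm33707 (3.21 ± 0.32, adjusted p = 0.033), and each moved the same way in both pairs. Gm33707, a processed pseudogene on chromosome 3 (60769887 to 60770455), was named after its values were seen. Its counts were 5 in control and 35 in knockout in one mix and 11 and 119 in the other. An unadjusted p under 0.05 was reached by 500 genes, where chance would give 699.

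Ccr6 (-0.96 ± 0.11, SE, adjusted p = 0.069), Gbp4 (0.81 ± 0.10, adjusted p = 0.091), Il17f (-0.72 ± 0.10, adjusted p = 0.12), Irf1 (0.78 ± 0.11, adjusted p = 0.15) and Nt5e (-1.60 ± 0.24, adjusted p = 0.21) did not pass in edgeR's quasi-likelihood test. All 5 passed with RLE scaling, which called 9 genes, and DESeq2 called 6, of which Il17f and Gbp4 were the additions. With no filter on low counts edgeR called 0 genes (472 at an unadjusted p under 0.05). The next by the fixed rule, which did not pass either, were Plac8 (0.60), Nkg7 (0.81), Rpl21 (0.52), Il12rb2 (0.40) and Gbp9 (0.68) on the higher side and Gap43 (-0.48), Il1r1 (-0.38) and Tspan6 (-0.42) on the lower side. Of the other fixed genes, Il22 (-0.46 ± 0.11), Il23r (-0.44 ± 0.20), Tbx21 (0.59 ± 0.13), Csf2 (-0.60 ± 0.18), Il2 (0.15 ± 0.08), Il10 (0.46 ± 0.19), Foxp3 (0.53 ± 0.27) and Mtor (0.09 ± 0.08) did not pass. Tnf had a value of 0.00 with either sign, depending on the scaling (-0.0034 with TMM and 0.0017 with library totals).

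Camera with a preset correlation called 12 of 34 tested lists for genotype in culture, 8 higher and 4 lower, and none passed with an estimated correlation (lowest adjusted p = 0.74 with an estimated correlation) or in fry (lowest adjusted p = 0.25). In simulated data with 5 changed lists, the estimated correlation recovered 0 in this design of 1 residual degree of freedom and the preset one recovered 5. Simulated genes varied independently, so this cannot show how the preset correlation performs on lists whose genes vary together. In these libraries the estimated correlation was 0.72 for ribosomal protein genes and 0.53 for respiratory chain genes. Th17 core genes had a median of -0.29 (camera adjusted p = 4.0e-26; adjusted p = 0.74 with an estimated correlation), with Il17a as the member that fell and 19 that did not pass (8 fell adjusted over the list alone). Cytotoxic and chemokine genes had a median of 0.43 (camera adjusted p = 1.8e-19; adjusted p = 0.74 with an estimated correlation), with Gzmb as the member that rose among 14 (4 rose adjusted over the list alone). Xcl1 (1.64 ± 0.27, SE) and Nkg7 (0.81 ± 0.15) were other members that did not pass. Interferon response genes had a median of 0.27 (camera adjusted p = 1.7e-14; adjusted p = 0.74 with an estimated correlation), with none of 34 past the threshold and 8 that rose adjusted over the list alone. Smaller medians were called for immediate-early (0.08, camera adjusted p = 2.6e-05), heat shock (0.10, 0.0044), Th1 (0.06, 2.6e-05), NF-κB (0.04, 0.0099), pathogenic Th17 (0.03, 0.0044), co-inhibitory (0.17, 0.038), sterol (-0.07, 0.0024), fatty acid synthesis (-0.06, 0.0023) and ribosomal protein genes (-0.04, 0.0044). With an estimated correlation the adjusted p was 0.74 for these lists and 0.85 for the ribosomal proteins. The medians had opposite signs in the mixes (TGF-β first) for Th1 (-0.05 and 0.19), pathogenic Th17 (-0.01 and 0.13), co-inhibitory (-0.01 and 0.16) and ribosomal protein genes (0.02 and -0.10). With no filter on low counts the calls of pathogenic Th17, Th1, fatty acid synthesis, co-inhibitory and heat shock genes ended (camera adjusted p from 0.086 to 0.54). Genes that respond to mTORC1 were not called (median -0.02 over 91 genes, camera adjusted p = 0.22), nor were glycolysis (-0.04, 0.22), respiratory chain (-0.02, 0.13) or Th2 genes (-0.13, 0.11).

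Within each cytokine mix the genotypes had 1 library each, so the values carry no replicate check. With TGF-β and IL-6, 23 of 9599 genes at 5 CPM or more differed at least 2-fold, 9 higher and 14 lower in knockout, and with IL-6, IL-1β and IL-23, 29 of 10003 did, 20 higher and 9 lower. Rora was in both sets. Gm33707 and the interferon-inducible gene Iigp1 (log2 ratios of 1.27 and 1.26) were in the set with IL-23 and under 5 CPM with TGF-β, and Iigp1 was named after its values were seen. The median log2 ratio of the Th17 core genes was -0.31 with TGF-β and -0.17 with IL-23, at percentile 0 among 10000 random lists of matched expression in either mix. The cytotoxic median was 0.43 and 0.40, at percentile 100 in both. Interferon genes had medians of 0.08 (percentile 98.4) and 0.31 (percentile 100), and respiratory chain genes 0.06 (percentile 100) and -0.08 (percentile 0). The random lists were matched on expression and not on how genes vary together. An extreme percentile can thus overstate how unusual a list is. Il23r was 33.1 CPM in control and 15.6 CPM in knockout with TGF-β and IL-6, and 91.2 and 89.6 CPM in the other mix. Il17f went from 3156 to 2188 CPM and from 1945 to 1032 CPM. Across 13983 genes the genotype log2 ratios in the mixes had a Pearson correlation of 0.02 and a Spearman correlation of -0.03, where genes are not independent replicates.

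Most tested genes of the cultured cells were called different between the cytokine mixes in the edgeR fit. With IL-6, IL-1β and IL-23 in place of TGF-β and IL-6, the cells had more RNA for Il22, interferon response, hypoxia and glycolysis genes and less for cell cycle genes, Il2 and Ccl20. Ccl20, which encodes a ligand of CCR6, fell from 1195 to 3.36 CPM in control and from 890 to 2.35 CPM in knockout cells. Il2 fell from 1171 to 28.3 CPM and from 1236 to 34.6 CPM, and Rora itself from 499 to 152 CPM in control. Of 13983 genes tested, 9765 passed an adjusted p of 0.05 in the edgeR fit, 5007 higher and 4758 lower with IL-6, IL-1β and IL-23. Of these, 2660 were at least 2-fold higher and 1748 at least 2-fold lower, and DESeq2 called 6867. The differences between mixes in control and in knockout cells had a Pearson correlation of 0.94 across genes.

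The largest increases were in genes that were nearly silent with TGF-β and IL-6. Ermn had 1 count there and 2242 in the other mix, a ratio of 2330 (95% counting interval 418 to 92088), and Cd93 had 2 and 3393 counts, a ratio of 1763 (488 to 14567). Adora3, Zbtb7c, Nyap2, Pmp22 and Stfa2 had no count with TGF-β and IL-6, and against a floor of 3 counts per library they were at least 57.5-fold, 53.3-fold, 45.9-fold, 45.9-fold and 39.0-fold higher. Enpp2, for autotaxin, rose by 9.44 ± 0.13 (SE). Besides Ccl20 (-8.51 ± 0.11) and Il2 (-5.26 ± 0.09), decreases were largest in Sema6d (-6.72 ± 0.17) and Adad1 (-4.99 ± 0.20), and in Gli3, Daw1 and Samd4, which had 1, 1 and 2 counts in the lower libraries against 281, 264 and 258. Gpr15 had 253 counts with TGF-β and 7 without, a ratio of 34.8 (16.6 to 87.4). Il22 had 7 counts with TGF-β and 1778 in the other mix, a ratio of 264 (128 to 658). Il23r (1.94 ± 0.20) and Csf2 (1.62 ± 0.19), genes tied to pathogenic Th17 cells, rose. Rora (-1.70 ± 0.07), Foxp3 (-2.50 ± 0.29), Tnf (-1.40 ± 0.08), Il17f (-0.89 ± 0.10) and Mtor (-0.75 ± 0.08) fell. For these 7 genes the largest adjusted p was 8.2e-05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Il17a (-0.07 ± 0.07), Tbx21 (0.29 ± 0.13), Il10 (-0.19 ± 0.19) and Ccr6 (0.00 ± 0.11, with the other sign under RLE scaling) did not pass.

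All 40 proliferation genes fell with IL-6, IL-1β and IL-23, among them the replication helicase genes Mcm2 (-2.29 ± 0.07, SE) and Mcm5 (-2.11 ± 0.07), with a median of -1.57 (camera adjusted p = 1.7e-29; adjusted p = 0.61 with an estimated correlation). Of 34 ribosome biogenesis genes 33 fell and 1 did not pass (median -1.03, camera adjusted p = 1.5e-15; adjusted p = 0.61 with an estimated correlation), with Utp20 at -2.26 ± 0.07. Ribosomal protein genes rose in 75 of 79 cases, with Rpl13a at 1.36 ± 0.07 (median 0.72, camera adjusted p = 4.7e-12; adjusted p = 0.63 with an estimated correlation). Interferon response genes rose in 30 cases, fell in 3 and did not pass in 1. Oas3 rose by 4.72 ± 0.12, Gbp4 by 3.71 ± 0.11 and Irgm1 by 2.91 ± 0.08 (list median 2.64, camera adjusted p = 3.4e-12; adjusted p = 0.61 with an estimated correlation). Hypoxia genes rose in 17 of 20 cases and fell in 2, with P4ha2 at 4.11 ± 0.12 (median 1.47, camera adjusted p = 4.1e-11; adjusted p = 0.61 with an estimated correlation). Glycolysis genes rose in 21 of 25 cases and fell in 2, with the glucose transporter gene Slc2a3 at 3.82 ± 0.08 (median 0.91, camera adjusted p = 8.0e-08; adjusted p = 0.61 with an estimated correlation). Th1 genes rose in 13 of 14 cases, with Il12rb2 at 3.47 ± 0.08 (median 1.51, camera adjusted p = 5.0e-08; adjusted p = 0.61 with an estimated correlation). Pathogenic Th17 genes rose in 14 of 19 cases and fell in 3, with Tgfb3 at 7.63 ± 0.18 and Gzmb at 3.69 ± 0.08 (median 1.62, camera adjusted p = 2.8e-06; adjusted p = 0.61 with an estimated correlation). The counts of these 8 lists were the same adjusted over the list alone.

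Weaker calls were made for 6 further lists, each with an adjusted p of 0.61 with an estimated correlation. Negative regulators of mTORC1 rose in 13 and fell in 7 of 24 cases, with Castor1 at 3.04 ± 0.10 (SE), Eif4ebp1 at 2.83 ± 0.08 and Ddit4 at 2.59 ± 0.09 (median 0.34, camera adjusted p = 0.022). Dendritic cell markers rose in 4 and fell in 1 of 8 (camera adjusted p = 0.0040), with H2-Ab1 at 3.22 ± 0.10 and Cd74 at 2.33 ± 0.09. Fatty acid oxidation genes rose in 12 and fell in 2 of 18 (0.016), naive and memory genes rose in 11 and fell in 5 of 17 (0.047), non-pathogenic Th17 genes rose in 2 and fell in 5 of 9 (0.0077), and immediate-early genes rose in 13 and fell in 17 of 33 (0.011). With no filter on low counts, all of these except the fatty acid oxidation list lost the call (camera adjusted p from 0.076 to 0.29), and the naive and memory list also lost it with RLE scaling (0.051). In fry, the Th1, pathogenic Th17, interferon and ribosomal protein lists did not pass (adjusted p from 0.068 to 0.077). Genes that respond to mTORC1 went both ways and were not called, with 41 that rose and 37 that fell of 91 (median 0.05, camera adjusted p = 0.53). The remaining 19 tested lists were not called. Among markers of other cells, the neutrophil gene Ly6g went from 3.30 and 3.89 CPM to 79.6 and 95.6 CPM, and the fibroblast gene Lum from 1.33 and 1.57 to 422 and 387 CPM. Only 4 of 13 neutrophil and 4 of 12 fibroblast markers were tested, with 3 that rose and 1 that fell in each list. Csf3r and Col3a1, other members of these lists, had no count in any cultured library, so Ly6g and Lum do not show such cells.

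**Figure D3:**
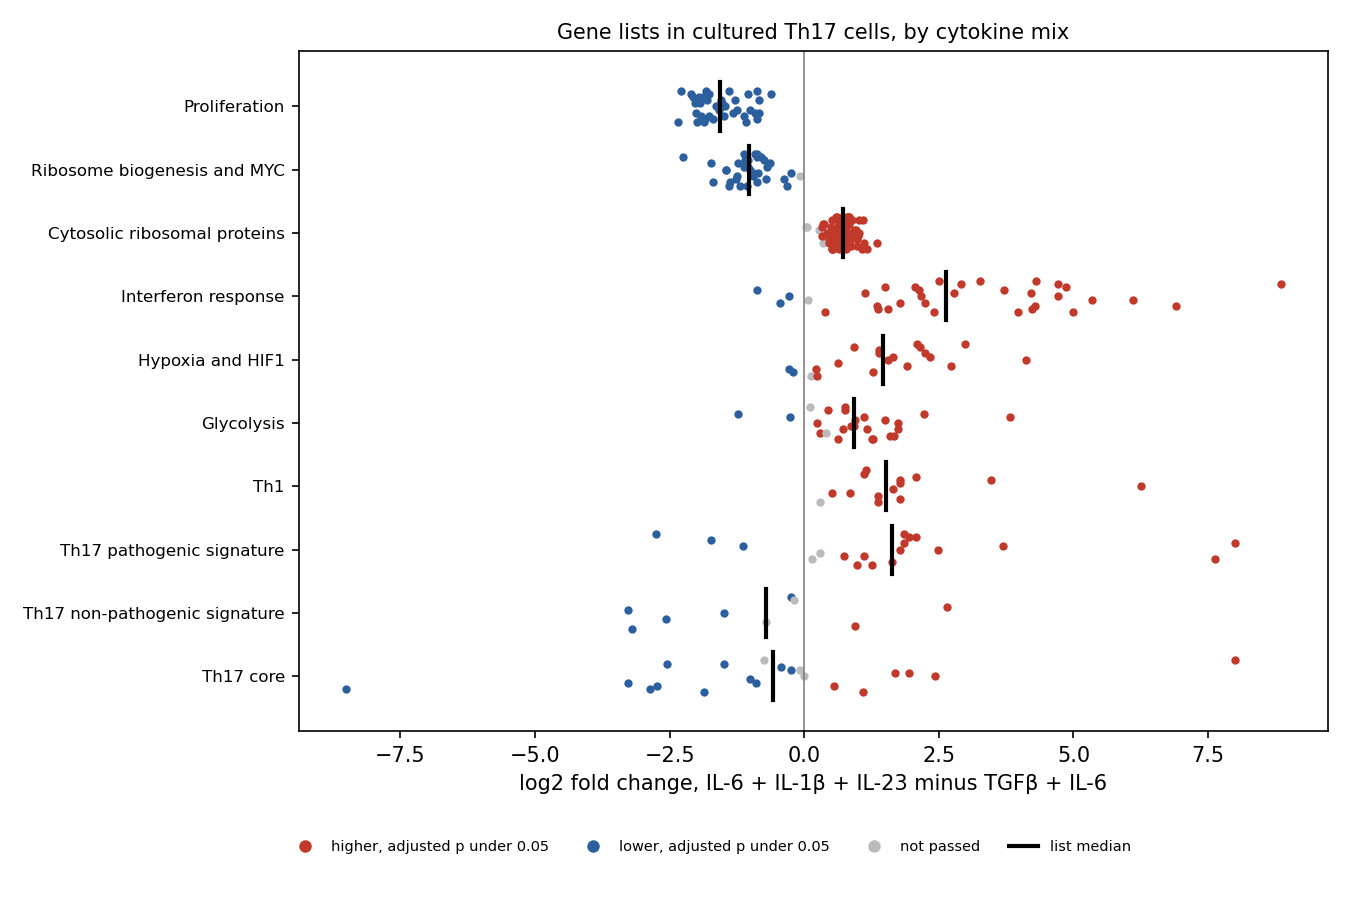
Log2 fold change (IL-6, IL-1β and IL-23 minus TGF-β and IL-6) of each tested gene in the fixed lists shown, over both genotypes; colour marks an edgeR adjusted p under 0.05 and bars mark list medians. All 40 proliferation genes lie below 0, and 30 of 34 interferon response genes were called higher.

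The genotype effect was compared between colitis and culture in a joint fit of all 8 libraries, which tests the difference of the log2 fold changes. Il17a and Il17f fell more in colitis, and the type 2 cytokine genes Il4 and Il13 had a more positive effect there. Of 14976 genes, 2579 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 1151 with a more positive and 1428 with a more negative effect in colitis, and DESeq2 called 1717. The difference was -0.95 ± 0.12 (SE) for Il17a, -1.26 ± 0.13 for Il17f and -0.93 ± 0.20 for Ccr6, and 3.06 ± 0.36 for Il4, 3.01 ± 0.21 for Il13 and 1.06 ± 0.13 for Gata3. For Rora it was 0.43 ± 0.12, since its RNA fell less in colitis. In culture Il4 had 16 and 33 counts (control and knockout) with TGF-β and IL-6, and 32 and 40 in the other mix. Il13 had 14 and 8, and 154 and 77, while Il5 had at most 1 in any library. The size of the differences for these cytokine genes thus depends on few counts in culture. The differences for Il22 (-0.35 ± 0.15), Il23r (-0.14 ± 0.30), Il2 (0.42 ± 0.16), Csf2 (0.37 ± 0.17), Foxp3 (-0.41 ± 0.21) and Mtor (-0.30 ± 0.13) did not pass. Across the 14976 genes the effects in colitis and in culture had a Pearson correlation of 0.04 and a Spearman correlation of 0.11.

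Camera called 12 of 40 tested lists for this difference, 3 with a more positive and 9 with a more negative effect in colitis, and none passed with an estimated correlation (lowest adjusted p = 0.32 with an estimated correlation). Ribosomal protein genes (61 of 79 more negative, median -0.67, camera adjusted p = 9.0e-32) and respiratory chain genes (34 of 75, median -0.43, 1.3e-13) led the list, followed by glycolysis genes (11 of 26, median -0.47, 4.3e-05), T cell markers (8 of 16, median -0.33, 1.8e-04), ATF4 genes (11 of 30, -0.38), Th17 core genes (9 of 20, -0.34), NF-κB genes (8 of 20, -0.26), cytotoxic genes (8 of 18, -0.38) and clock genes (4 of 18, -0.23, 0.035). Th2 (6 of 12, median 0.99, camera adjusted p = 9.8e-04), epithelial (4 of 12, median 3.08, 0.018) and B cell and plasma cell genes (2 of 11, median 1.51, 0.035) were more positive. Genes that respond to mTORC1 were not called (27 more negative and 9 more positive of 92, median -0.13, camera adjusted p = 0.054). Interferon response genes were not called either (2 more negative and 2 more positive of 35, median -0.02, camera adjusted p = 0.95). Among 11983 genes tested in both comparisons, both genes called lower in culture, Il17a and the deleted gene Rora, were also called lower in colitis. Both called higher, Gzmb and Gm33707, were also called higher, where 0.350 was the expected overlap (Fisher's exact test, p = 0.031). For lower genes, with the deleted gene included, Fisher's exact test gave p = 0.044. With 2 genes each, these are the smallest p-values possible, and they were not adjusted.

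**Figure D4:**
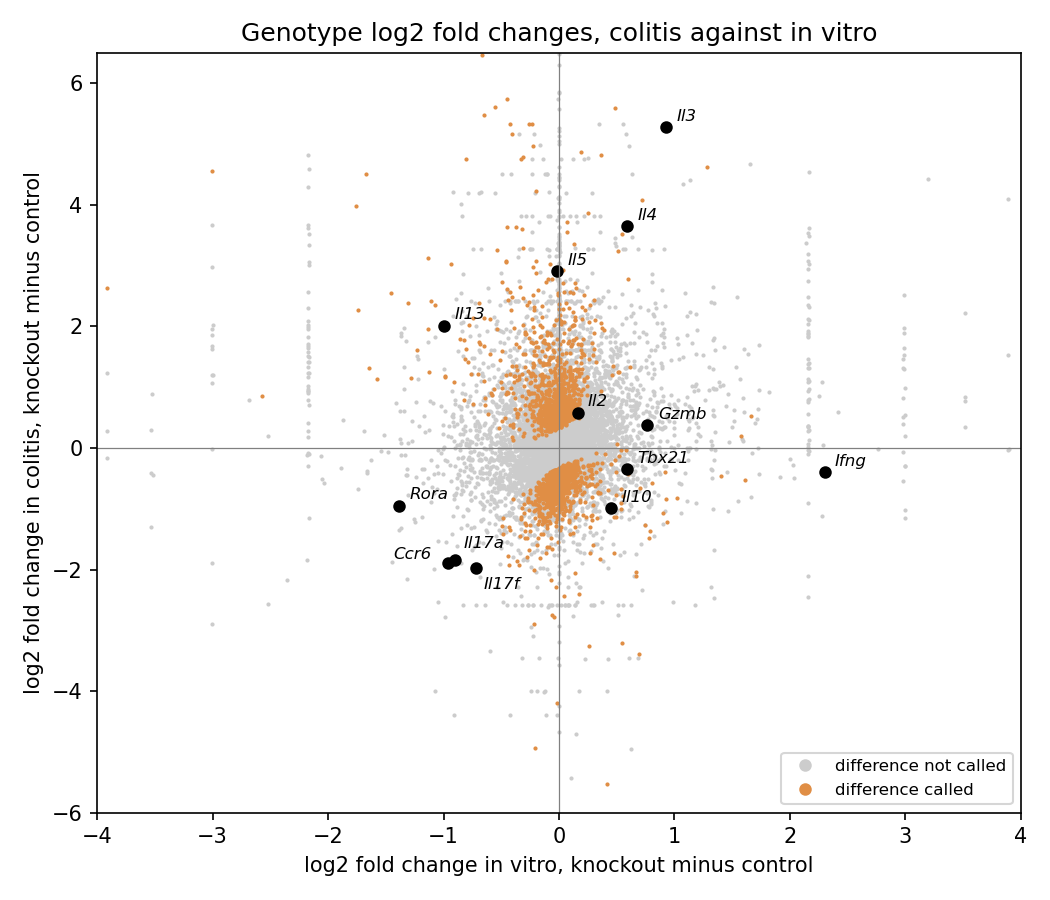
Genotype log2 fold change (knockout minus control) of 14976 genes in colitis (vertical axis) against that in culture (horizontal axis), with orange for genes whose difference passed an edgeR adjusted p of 0.05; 35 genes lie outside the axes. Rora, Il17a, Il17f and Ccr6 sit below 0 on both axes, and Il4, Il5 and Il13 rise in colitis, where the gene-wide Pearson correlation was 0.04. Il5 had at most 1 count in any cultured library, so its horizontal position carries no weight.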

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

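The test of basophil and mast cell gene levels and the test of power in culture were chosen only after the result was seen, and the other tests in this part were chosen before.

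The genotype effect differed between colitis and cultured cells for 2579 genes in edgeR's quasi-likelihood test of that difference (Benjamini-Hochberg). The 16 genes with the largest differences by the fixed rule included many with few counts in some libraries. Differences toward a higher value in colitis were 5.08 for Ighg1, 4.68 for Cyp11a1, 4.44 for Car8, 4.35 for Il3, 3.97 for Hmgn3 and 3.62 for Trpm6 (log2 scale). Cldn4 and Csf2rb had fitted differences of 7.56 and 4.92. These rest on cultured knockout libraries with no count, so their size and rank do not hold. Cldn4, Ighg1 and Csf2rb had at most 6 counts in any cultured library, so their differences depend on few counts. Hmgn3 had 2 and 1 counts in colitis control and 7 and 23 in colitis knockout, so its difference does too. In culture Csf2rb had 0 and 5 counts in control and Cldn4 had 1 and 1, and both had 0 in each knockout library. No size can thus be given for their effect in culture, while the effect in colitis was 0.70 for Csf2rb and 4.56 for Cldn4. Differences toward a lower value were -2.77 for Serp2, -2.74 for Krt83, -2.70 for Ifng, -2.69 for Prss12, -2.25 for Ms4a4c, -2.14 for Penk, -1.97 for Nmnat2 and -1.87 for Lrrk1. Ifng had 3 and 17 counts (control and knockout) with TGF-β and IL-6 and 2 and 9 in the other mix, against 14754 or more in colitis. Lrrk1 no longer passed in DESeq2 (adjusted p = 0.089).

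Of the fixed genes, Rora (0.43), Il17a (-0.95), Il17f (-1.26), Tbx21 (-0.93), Tnf (-0.48), Il10 (-1.45) and Ccr6 (-0.93) also differed. Cell source, replicate structure and annotation all changed together between colitis and culture, so the cause of these differences was not tested.

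Th2 cytokine genes rose in the colitis knockout libraries, with a median of 2.91 for Il4, Il5 and Il13. Basophils or mast cells were argued against by level, since the highest of Cpa3, Fcer1a, Ms4a2 and Mcpt8 reached 0.0771% of the Il4 level in knockout, with Cpa3 at 0.330 CPM. An earlier form of this test, written before, pointed the other way, since the median of the 5 tested of 14 listed genes was 3.98, but it rested on trace genes such as Cd200r3 (3.74 CPM) and Mcpt1 (4.02 CPM). Type 2 innate lymphoid cells may contribute and stay open, because 8 tested of 10 listed genes had a median of 0.73 with quartiles of -0.32 and 0.99, and T cells express several of them. An effect of the genotype on the T cells themselves also stays open, and the cells had been isolated as CD4+.

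Ribosomal protein genes were lower in the colitis knockout libraries, and 3 technical explanations were argued against as its whole cause. For length and GC content this holds only for the trend as fitted. After removing the trend with transcript length and GC content the median was -0.51 (quartiles -0.66 and -0.34). The trend itself gave -0.20, so it may account for part. It was fitted without the ribosomal protein and respiratory chain genes, on the longest coding transcript of each gene. Both choices can make the correction too small, so a stronger length bias was not tested. With library totals the median was -0.49. A lower share of T cells would lower T cell markers as much, but their median lay 0.36 above that of the ribosomal protein genes, beyond the interquartile range of 0.207, and 16 of 16 markers lay above it. If marker levels per T cell were unchanged, the same values argue against RNA from other cells with few ribosomal transcripts as the whole cause. Such RNA may account for part. Reads shared with pseudogenes and a genotype effect were not separated.

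Many more genes were called in colitis than in culture, and lower power in culture was argued against as the whole cause. The share of genes 1.5-fold apart in the same direction in both pairs was 10.4% of 9115 genes in colitis and 0.0916% of 9825 in culture, a ratio of 113. The culture pairs were different cytokine mixes, so a change in 1 mix alone was not counted, and the ratio can overstate the contrast. Single pairs, which need no match between mixes, gave 15.4% and 17.0% in colitis and 1.48% and 1.09% in culture. The colitis replicates may share technical steps within a group that the cultured libraries did not, and that stays open together with a larger genotype effect in the colon. RNA from other cell types, whose markers rose in the colitis knockout libraries (epithelial median 3.21), also stays open.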

How the results depend on the processing

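Library totals in place of a scaling factor were chosen for single genes and their counts only after the data were seen, and the other settings in this part, library totals for list medians included, were chosen before. Of 67 named genes in colitis, 61 to 67 kept their direction and their side of the threshold under each setting, of 49 for genotype in culture 43 to 47, and of 52 for the cytokine mix 51 or 52. No gene called in a comparison was called in the opposite direction under any setting tried.

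In colitis, RLE scaling gave 5179 calls, no filter 5569 and library totals 5548, and these kept 99.0%, 96.6% and 73.9% of the 5173 calls. DESeq2 gave 3448 (1423 higher and 2025 lower) and kept 66.0%, and the cause was not tested. Leaving out 1 library gave 4041 to 4889 calls and kept 74.0% to 84.4%, with 14 to 17 lists. In these fits the lone library is assumed to vary like the other group. The shared numbers may not pair samples. A replicate block gave 6230 calls, kept all 5173 and called 16 lists. Macrophage markers were lost there (camera adjusted p = 0.077) and Mtor passed (edgeR adjusted p = 0.049), while deviations within the numbered pairs correlated at 0.153. With library totals at least 32 of 39 list medians moved by more than the spread between replicates, and 12 changed sign, of which 10 were for lists not called. Of the called ones, the median of mTORC1-responsive genes reversed to 0.079 and that of ROR and clock genes reversed to 0.11, by construction of the shift.

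With an estimated correlation 0 lists passed in colitis, 0 for genotype in culture and 0 for the cytokine mix. In culture, fry passed 0 lists for genotype. Simulated lists of the culture design gave 0 recovered with an estimated correlation as well, so that setting says little there. In the simulated colitis design the estimated correlation recovered 5 of 5 changed lists. The loss of all 17 colitis calls is thus a limit of those calls. The simulated genes varied independently, so the preset correlation was not tested on lists whose genes vary together either. For genes changed by genotype in culture, edgeR gave 9 with RLE scaling, 9 with library totals and 0 with no filter, which tests 26228 genes in place of 13983, while 472 had an unadjusted p under 0.05 and DESeq2 called 6. Without the filter Rora had an adjusted p of 0.094, Il17a 0.16 and Gzmb 0.95. For the cytokine mix the settings gave 6867 to 9936 calls. For the difference between colitis and culture, RLE scaling gave 2607, no filter 2735 (with Il2 past the threshold at 0.0075) and DESeq2 1717, and the cause was not tested.

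Single pairs at a floor of 1 CPM had 133 genes 2-fold apart with TGF-β and IL-6 and 145 in the other mix, since genes with few counts enter. Depth limits such genes, and leaving out a library could not be run in culture, where each group has 1.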

Other observations

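No explanation was tested in this part, and Gm33707 and Iigp1 were singled out only after their values were seen.

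The pseudogene Gm33707 was higher in each knockout library than in its controls. Its counts were 0 and 2 in colitis control and 29 and 25 in colitis knockout, 5 and 35 with TGF-β and IL-6, and 11 and 119 with IL-6, IL-1β and IL-23. Iigp1 rose in colitis from 24.1 to 35.2 CPM and had 12 and 32 counts in one mix and 31 and 78 in the other. Gzmb had 409 and 395 CPM in colitis control and 533 and 516 CPM in colitis knockout.

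Penk, which encodes proenkephalin, was abundant in colitis, with 511 CPM in control and 355 CPM in knockout. In culture it had 6 and 21 counts with TGF-β and IL-6, and 19 and 57 with IL-6, IL-1β and IL-23, the opposite direction. Il3 had 22 and 42 counts and 35 and 68 counts in the same cultures, the same direction as in colitis. Il24, a member of the Th2 list, went from 1.96 to 887 CPM in control and from 1.95 to 783 CPM in knockout cells between the mixes, and Gpr15 from 6.97 to 0.130 CPM in knockout cells.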
